A study of Homo sapiens with 15 samples.

How the data were processed

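The series held 15 RNA libraries of CD4+ T cells from human blood in 3 groups of 5: PD1hi, CD25hi and DN. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted from 100 ng of RNA with RiboMinus, and libraries were made with the Ion Total RNA-seq kit v2. The submitters' processing notes name Picard, HTSeq 0.5.4, limma and the builds hg19 and GRCh37, without giving the role or order of each. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes could not be told from those of the named gene, and reads shared between paralogs, as in the HLA and histone families, were not separated.

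The deposited table gave 1 signal value per gene and library, scaled by DESeq according to its name. Subtracting 1 from each value and multiplying by 1 factor per library gave whole numbers within 0.005 in 100% of values in every library. Those factors equalled the median-of-ratios size factors of the recovered reads, so the deposited signal was reads divided by the size factor, plus 1. The value used here is the deposited value minus 1, called scaled reads, and log2 of scaled reads plus 1 is therefore the log2 of the deposited value. The table held 27468 rows, of which 4 counted reads not assigned to a gene. These 4 were left out: reads in no gene were 56.6 to 68.5% of a library's reads, reads with more than 1 alignment 12.1 to 15.3%, reads not aligned 0.733 to 6.34% and ambiguous reads 0.207 to 0.420%. Of the 27464 gene rows, 18 carried a symbol that stood on more than 1 row, and gene symbols were used as deposited, with no coordinates.

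All reads of a library numbered 65.9 to 96.7 megareads (M), and reads assigned to genes 10.5 to 22.4 M. Total reads averaged 82.1 ± 10.2 M in PD1hi, 79.7 ± 3.67 M in CD25hi and 84.3 ± 10.6 M in DN (SD, n = 5). The 10 most abundant genes took 9.70 to 13.3% of a library's gene reads, and MALAT1 1.29 to 3.33%. At these depths a gene with no reads in a library may still have had up to 3 reads, a mean of 2.93 scaled reads over the libraries. Floors and p values cover counting error and the spread between these libraries. No 2 libraries of a group were copies of each other: in 30 pairs chi-square per degree of freedom was 47.7 to 209.

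Genes with a mean of at least 10 scaled reads over the 15 libraries were tested, 17340 of 27464. Log2 of scaled reads plus 1 was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 15 libraries and empirical Bayes moderation with a trend. The 3 comparisons were PD1hi against DN, CD25hi against DN and PD1hi against CD25hi, each adjusted by Benjamini-Hochberg and called at an adjusted p under 0.05. Replicate numbers were shared by the groups and the experiment numbers were 6, 7 and 8, with 1, 2 and 2 libraries per group. Same-numbered libraries of the 3 groups had the same experiment number and, where given, the same further tag in their titles. Nothing in the labels stated what the tag meant or that same-numbered libraries came from 1 donor, so no pairing was used in the test. Differences were recomputed within each experiment.

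Before the data were examined, the groups, comparisons, gene lists, alternatives and the rule for named genes were fixed. The rule named the sort markers CD4, PDCD1 and IL2RA and also FOXP3 whatever their result. Per comparison it took the 8 called genes with the largest positive and the 8 with the largest negative log2 difference that differed in the same direction in each of the 5 same-numbered pairs. It left out unnamed loci and clones, pseudogene symbols, T cell receptor and immunoglobulin segments, HLA genes, small RNAs, and genes that mark sex. Per list described it took up to 4 members, those called in order of adjusted p or else those with the lowest p, and for lists of other cell types up to 3 members with the highest mean. Genes named for a comparison were also given in the others where a list held them.

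The lists were follicular helper, regulatory T cell, inhibitory receptor, costimulatory receptor, naive and central memory, cytotoxic effector, Th1, Th2, Th17, exhaustion transcription factor, homing receptor, cell cycle, interferon response, immediate early, MHC class II, T helper cytokine, glycolysis, oxidative phosphorylation, B cell, monocyte, CD8 T cell, natural killer cell, platelet, erythroid and dendritic cell, with mitochondrially encoded, ribosomal protein, histone and small RNA genes taken by symbol. PDCD1 and IL2RA were kept out of the lists of inhibitory receptor, follicular helper and regulatory genes. Lists with at least 3 measured genes, 27 in all, were tested with camera at a preset correlation of 0.01 between genes, and the 27 p values of a comparison were adjusted together. Camera with an estimated correlation and fry were run as alternatives.

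The test was tested on simulated data for PD1hi against DN with 15996 genes. Of genes changed by 1 on the log2 scale 2 of 61 were called, of those changed by 2, 20 of 75, and of those changed by 4, 24 of 64. With a mean of at least 1000 scaled reads the calls were 1 of 8, 10 of 10 and 6 of 6. Of 15809 unchanged genes 4 were called, and in a simulated comparison without change none of 15996. A raised list passed the threshold and none of 20 unchanged lists did. Genes were simulated independently of each other, so this does not show how the list test behaves where the genes of a list are correlated.

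Alternatives changed 1 choice at a time: a pseudocount of 0.5 or 5, no filter or a mean of at least 50, equal totals, upper quartile scaling, quantile normalization, a term for the replicate number, a term for the experiment, only the 2 groups compared, a constant prior variance, robust moderation, an added limit of 1 on the log2 difference, and each library left out. On the recovered reads, edgeR 4.0.16 with TMM and quasi-likelihood called 392, 199 and 51 genes in PD1hi against DN, CD25hi against DN and PD1hi against CD25hi, and DESeq2 1.42.0 called 1062, 681 and 293. Chosen after seeing the data were fits without the 3 libraries least correlated with the rest (DN replicates 4 and 5 and PD1hi replicate 4), with the number of genes detected as a covariate, with a mean of at least 1000, and within experiments 7 and 8. For each comparison 100 of the 126 possible divisions of its 10 libraries into equal groups were tested, the real one included. Values of 3 genes chosen by the same rules are not reported here.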

Results

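Total RNA was sequenced from 3 populations of CD4+ T cells sorted from human blood, with 5 libraries per population. PD1hi cells carried high surface PD-1, an inhibitory receptor encoded by PDCD1, and no CD25. CD25hi cells, the regulatory T cell (Treg) population, carried high CD25, the alpha chain of the interleukin-2 receptor encoded by IL2RA. DN cells carried neither marker and stood for conventional T cells. The comparisons asked how the profile of PD1hi cells related to those of conventional T cells and of Tregs. Replicate 1 of each population came from experiment 6, replicates 2 and 3 from experiment 7, and replicates 4 and 5 from experiment 8.

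Reads assigned to genes numbered 10.5 to 22.4 megareads (M) per library. The PD1hi libraries, replicates 1 to 5, held 22.3, 17.2, 14.2, 14.5 and 18.4 M gene reads. The CD25hi libraries held 22.4, 12.5, 14.7, 14.5 and 19.6 M, and the DN libraries 13.7, 17.9, 13.7, 10.5 and 12.9 M. Group means were 17.3 ± 3.28 M for PD1hi, 16.8 ± 4.08 M for CD25hi and 13.7 ± 2.68 M for DN (SD, n = 5 each). Between 14868 and 21048 genes had at least 1 read in a library. Gene values below are scaled reads (reads divided by the library's size factor), as mean ± SD over the 5 libraries of a group. Adjusted p values come from the limma fit over 17340 genes. A gene with no reads in a whole group was set against a floor of 3 reads per library, and such floors cover counting error only.

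CD4 transcripts were abundant in all 3 groups, with 9968 ± 1765 scaled reads in PD1hi, 7064 ± 1877 in CD25hi and 6949.9 ± 1605 in DN cells. They did not pass the test in any comparison (adjusted p = 0.151 for PD1hi against DN, 0.978 for CD25hi against DN and 0.452 for PD1hi against CD25hi). PDCD1 had 85.0 ± 65.9 scaled reads in PD1hi cells against 12.6 ± 14.6 in DN cells and 14.4 ± 22.8 in CD25hi cells. It was higher in PD1hi than in DN in 5 of 5 same-numbered pairs, with a log2 difference of 3.29 that missed the threshold (SE 1.21, adjusted p = 0.155). IL2RA had 2981 ± 1625 scaled reads in CD25hi cells, 38.8 ± 58.6 in PD1hi cells and 56.8 ± 65.5 in DN cells. FOXP3, the lineage-defining transcription factor of Tregs, had 583 ± 369 in CD25hi cells, 18.8 ± 25.9 in PD1hi cells and none in DN cells. Both IL2RA (adjusted p = 0.00893) and FOXP3 (at least 178-fold, adjusted p = 0.000468) were higher in CD25hi than in DN cells in 5 of 5 pairs. PD1hi and DN cells did not differ detectably in IL2RA (log2 difference -0.92, adjusted p = 0.771) or FOXP3 (reads in 2 of 5 PD1hi libraries, adjusted p = 0.36). Single libraries moved some of the low means by over 1.5 times. Without the library in brackets IL2RA averaged 35.8 (DN replicate 2) and 13.2 (PD1hi replicate 1), FOXP3 10.5 (PD1hi replicate 3), and PDCD1 4.35 (CD25hi replicate 4) and 8.14 (DN replicate 5).

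**Figure D1:**
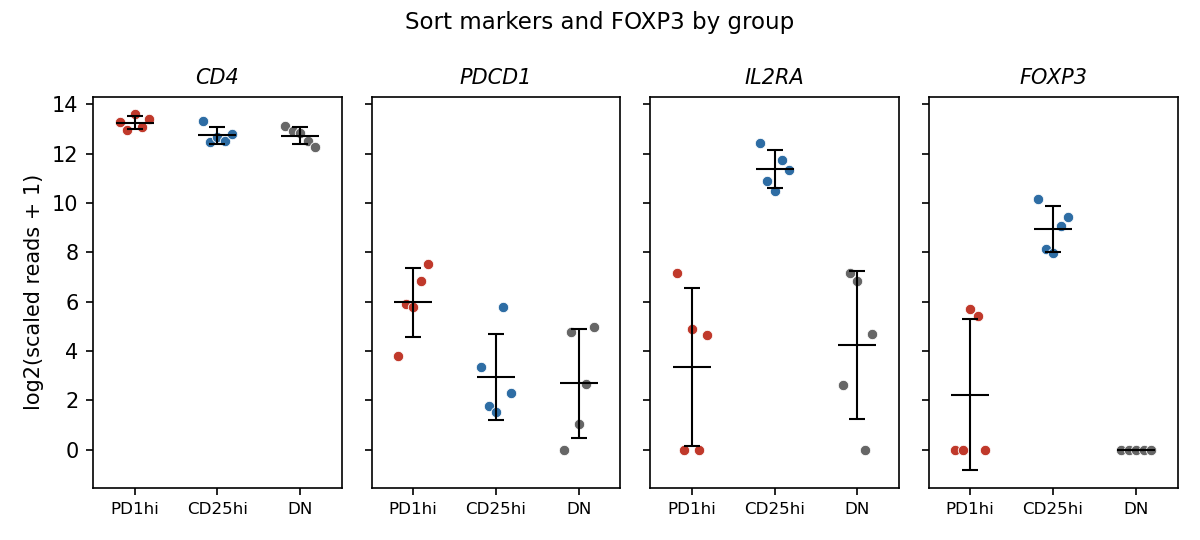
Values of CD4, PDCD1, IL2RA and FOXP3 on a log2 scale (log2 of scaled reads plus 1) in the PD1hi, CD25hi and DN groups; each point is a library, and the bars give the mean and SD of 5 libraries. IL2RA averaged 2981 scaled reads in CD25hi cells against 38.8 in PD1hi cells, and PDCD1 averaged 85.0 in PD1hi cells against 12.6 in DN cells.

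PD1hi cells differed from DN cells in 579 genes, of which 354 were higher and 225 lower in PD1hi. The genes higher in PD1hi cells included those of follicular helper cells, of cytotoxic and Th1 effector cells and of the cell cycle, while those of naive and central memory cells were lower. Among the largest rises was EOMES (361 ± 137 scaled reads against 14.8 in DN, adjusted p = 0.00667), a T-box factor of effector and memory cells. Granzyme genes rose as well, GZMA to 2691 ± 2481 from 92.2 (adjusted p = 0.0135) and GZMH to 1352 ± 1163 from 36.0 (adjusted p = 0.0208). The thrombin receptor gene F2R had 531 ± 352 scaled reads in PD1hi against 11.6 in DN cells (adjusted p = 0.000404). TK1, a thymidine kinase of dividing cells, had 398 ± 434 against 7.07 (adjusted p = 0.000891). DTHD1, which encodes a death domain protein, and RCAN2, a calcineurin regulator, had no reads in DN cells. In PD1hi cells they were at least 121-fold (adjusted p = 0.000755) and at least 38.9-fold (adjusted p = 0.00373) higher. Without PD1hi replicate 1 the PD1hi mean of GZMA was 1614 (adjusted p = 0.041) and that of TK1 219 (adjusted p = 0.00448). The PD1hi mean of RCAN2 fell from 127 to 76.9 without PD1hi replicate 4. Leaving out 1 DN library also moved DN means, to 0 (replicate 2) for EOMES, 0.996 (replicate 5) for F2R, 38.5 (replicate 1) for GZMA, 9.69 (replicate 5) for GZMH and 0 (replicate 1) for TK1.

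The largest falls in PD1hi cells were in genes with few or no reads left there. EDAR, a receptor of the TNF receptor family, had 12.3 scaled reads in PD1hi against 752 ± 276 in DN cells (adjusted p = 0.00229). TNFRSF10D, a decoy receptor for TRAIL, had 11.1 against 582 ± 124 (adjusted p = 0.000151). PCSK5, a proprotein convertase gene with 519 ± 35.2 scaled reads in DN cells, had a log2 difference of -7.69 (adjusted p = 0.000505). Log2 differences were -7.48 for the desmosomal cadherin gene DSC1 (adjusted p = 0.00851) and -7.13 for NBEA, a vesicle trafficking gene (adjusted p = 0.00331). They were -6.68 for the RING finger gene RNF175 (adjusted p = 0.000272) and -6.66 for CACHD1, a calcium channel modulator gene (adjusted p = 0.00216). SORCS3, a sorting receptor gene, had no reads in PD1hi cells and was at least 49.6-fold lower than in DN cells (adjusted p = 0.000308). Without PD1hi replicate 3 the PD1hi mean was 0 for EDAR and 1.20 for TNFRSF10D.

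Of the follicular helper genes, 7 of 19 measured members rose in PD1hi cells and none fell (11 higher when adjusted over the list alone), with a median log2 difference of 1.39 (camera adjusted p = 9.08e-12, 0.00244 with an estimated correlation). TOX, a nuclear factor of chronically stimulated and follicular helper T cells, had 3159.7 ± 1399 scaled reads against 269 ± 83.8 in DN cells (log2 difference 3.47, SE 0.39, adjusted p = 7.35e-05). The inhibitory receptor gene TIGIT had 2723 ± 1026 against 205 ± 129 (log2 difference 3.86, SE 0.45, adjusted p = 9.42e-05). MAF, a transcription factor that drives IL-21, rose by 2.57 on the log2 scale (adjusted p = 0.000312), and SH2D1A, which encodes the adaptor SAP, by 1.57 (adjusted p = 0.00486). Among inhibitory receptors 1 of 14 passed the test, TIGIT (4 higher when adjusted over the list alone). That list had an adjusted p = 0.00151 (0.0181 with an estimated correlation). Of the factors linked to exhaustion, 5 of 12 rose (7 higher and 1 lower when adjusted over the list alone). The list had an adjusted p = 1.13e-07 (0.00121 with an estimated correlation). Its members included PRDM1, which encodes Blimp-1, with 2704 ± 1189 scaled reads against 681 ± 399.7 (adjusted p = 0.00412).

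Of the cytotoxic effector genes, 12 of 24 rose in PD1hi cells and none fell (16 higher when adjusted over the list alone), with a median log2 difference of 3.87 (adjusted p = 1.35e-16, 0.00885 with an estimated correlation). The chemokine gene CCL5 had 15737 ± 4058 scaled reads in PD1hi and 847 ± 620.3 in DN cells (log2 difference 4.75, SE 0.58, adjusted p = 0.000151). CST7, which encodes the granule protein cystatin F, had 3112 ± 456 against 229.6 ± 149 (adjusted p = 0.000242). KLRB1, which encodes CD161, had 3436 ± 842 against 798 ± 374 (adjusted p = 0.000325), and the chemokine gene CCL3 was at least 25.4-fold higher (adjusted p = 0.00285). Of the markers of CD8 T cells and natural killer (NK) cells, CD8A had 16.7 scaled reads and FCGR3A 10.9 in the same PD1hi libraries. Others were higher, CRTAM of the CD8 list at 239 ± 134 against 65.3 ± 72.1 in DN cells (adjusted p = 0.175) and KIR3DL2 of the NK list at 80.5 ± 101 against 5.00 (adjusted p = 0.49). In PD1hi against DN none of the 7 measured NK markers was called in limma (1 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2). The NK list had a median of -0.68, a mean of -0.09 and a test in the positive direction (adjusted p = 0.883). Of the Th1 genes, 5 of 11 rose (8 higher when adjusted over the list alone). The Th1 list passed as a whole (adjusted p = 3.3e-09, 0.00105 with an estimated correlation). CXCR3, a chemokine receptor of Th1 cells, had 1896 ± 757 scaled reads against 195 ± 225 (adjusted p = 0.00222), and TBX21, which encodes the Th1 factor T-bet, 138 ± 90.9 against 1.65 (adjusted p = 0.00302). Without DN replicate 5 the DN mean was 95.3 for CXCR3 and 0 for TBX21. The PD1hi mean of CCL3 fell from 83.2 to 42.3 scaled reads without PD1hi replicate 1. The mean of CRTAM was 38.0 without DN replicate 3, and that of KIR3DL2 44.6 without PD1hi replicate 5 and 2.35 without DN replicate 1.

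Of the naive and central memory genes, 15 of 24 fell in PD1hi cells and none rose (20 lower when adjusted over the list alone), with a median log2 difference of -1.62 (adjusted p = 3.22e-16, 0.00067 with an estimated correlation). CCR7, the lymph node homing receptor, had 5888 ± 1810.2 scaled reads in PD1hi and 27218 ± 7742 in DN cells (log2 difference -2.21, SE 0.23, adjusted p = 7.35e-05). The kinase gene TXK fell by 2.09 on the log2 scale (adjusted p = 7.35e-05), LEF1, a factor of naive T cells, by 1.41 (adjusted p = 0.000208) and ACTN1, an actin crosslinker gene, by 2.64 (adjusted p = 0.000272). Of the homing receptors 5 rose and 1 fell among 21 measured (7 higher and 2 lower when adjusted over the list alone). The list had an adjusted p = 0.000262 (0.0553 with an estimated correlation), and the integrin gene ITGB1 had 6636 ± 1106 against 1665 ± 495 scaled reads (adjusted p = 7.35e-05). Of the cell cycle genes 5 of 30 rose and none fell (19 higher when adjusted over the list alone). Their median was 3.28 (adjusted p = 3.52e-14, 0.00885 with an estimated correlation). Among genes with a mean of at least 1000 it was 0.76 and the call was lost (adjusted p = 0.215). TOP2A, a topoisomerase of dividing cells, had 889.6 ± 641 against 102 (adjusted p = 0.00419). BUB1B, a spindle checkpoint kinase gene, was at least 30.3-fold higher (adjusted p = 0.00526).

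**Figure D2:**
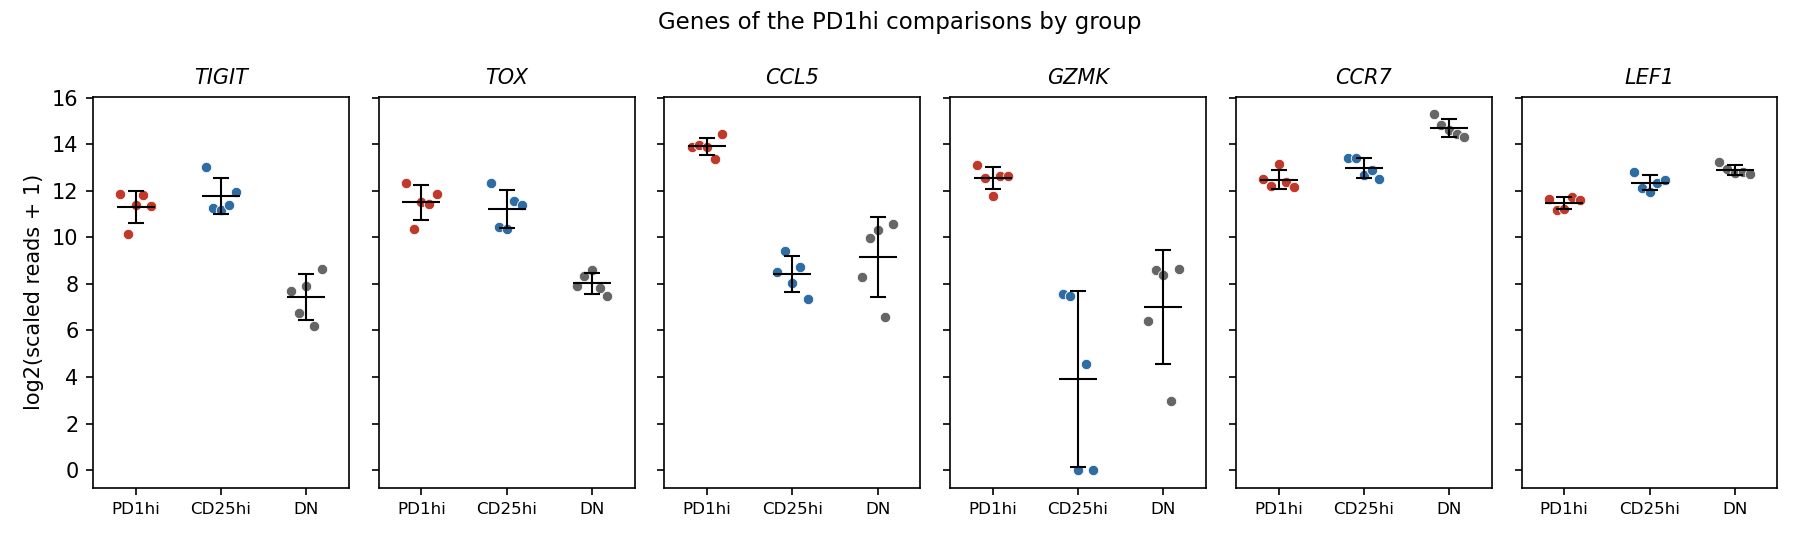
Values of TIGIT, TOX, CCL5, GZMK, CCR7 and LEF1 on a log2 scale (log2 of scaled reads plus 1) in the PD1hi, CD25hi and DN groups; each point is a library, and the bars give the mean and SD of 5 libraries. TIGIT averaged 2723 scaled reads in PD1hi and 3952 in CD25hi cells against 205 in DN cells, and CCL5 averaged 15737 in PD1hi cells against 378 in CD25hi cells.

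Treg-associated genes also rose in part in PD1hi cells: 9 of 28 measured members were higher than in DN cells and none was lower (13 higher when adjusted over the list alone), with a median log2 difference of 1.73 (adjusted p = 2.31e-10, 0.00507 with an estimated correlation). These members were TNFRSF9, TNFRSF1B, FCRL3, BATF, IL2RB, DUSP4, NCF4, IL10RA and GBP5. Whether they rose through activation or through a Treg program was not tested. IL2RB, the beta chain of the interleukin-2 receptor, had 1167 ± 280.0 scaled reads against 207 ± 134 (log2 difference 2.70, SE 0.39, adjusted p = 0.000488). The interleukin-10 receptor gene IL10RA had 5625 ± 828 against 2071 ± 647 (adjusted p = 0.000665), and TNFRSF1B, which encodes the TNF receptor TNFR2, 2192 ± 531 against 295 ± 209 (adjusted p = 0.000887). Among costimulatory receptors 2 of 11 rose, the adhesion receptor gene CD2 and TNFRSF9, which encodes 4-1BB (3 higher when adjusted over the list alone). That list had an adjusted p = 0.00492 (0.0538 with an estimated correlation). KLRB1 was the 1 riser among 10 Th17 genes (2 higher when adjusted over the list alone; list adjusted p = 0.00159, 0.055 with an estimated correlation). None of the 7 Th2 genes passed the test in limma (1 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2; list median 0.39, adjusted p = 0.3).

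The test called 579 genes in limma, and 3055 had an unadjusted p under 0.05. Of the 579 genes, 573 differed in the same direction in experiment 6, 579 in experiment 7 and 579 in experiment 8. The genes were called on these same libraries, so this agreement was largely built in and is no independent replication. Within experiments 7 and 8 alone, with 2 libraries per group, limma called 0 genes, and 1794 and 3000 had an unadjusted p under 0.05. A fit without PD1hi replicate 5 called 360 genes, 223 higher and 137 lower, and a fit without DN replicate 4 called 142 lower genes. Without the 3 libraries least correlated with the rest, a choice made after seeing the data, 251 were called. CD2 lost its call without DN replicate 4 (adjusted p = 0.0541). GZMH lost it without any 1 of PD1hi replicates 1, 3 and 5 and DN replicates 1, 3 and 4 (adjusted p 0.0521 to 0.0682). TNFRSF9 lost it without any 1 of PD1hi replicates 1 and 4 and DN replicates 1, 2 and 3 (adjusted p 0.0530 to 0.0592). TNFRSF9 was higher in 4 of 5 same-numbered pairs.

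CD25hi cells differed from DN cells in 293 genes, of which 219 were higher and 74 lower in CD25hi. Treg genes had the highest share of called members among the 27 lists tested: 21 of 28 measured members rose and none fell (27 higher when adjusted over the list alone), with a median log2 difference of 4.26 (adjusted p = 6.79e-38, 4.37e-05 with an estimated correlation). STAM, a signal adaptor gene, had 4349 ± 1242 scaled reads against 629 ± 193 in DN cells (log2 difference 2.78, SE 0.29, adjusted p = 3.86e-05). RTKN2, a gene high in Tregs, had 6174 ± 2680.3 against 318 ± 222 (log2 difference 4.56, SE 0.56, adjusted p = 0.000179). IL2RB rose by 2.97 on the log2 scale (adjusted p = 0.000309). IKZF2, which encodes the Treg factor Helios, had 3196 ± 799.6 against 89.0 ± 77.3 (adjusted p = 0.00194), and ENTPD1, the ectonucleotidase CD39, 1461 ± 524 against 376 ± 130.5 (adjusted p = 0.0016).

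Among the largest rises in CD25hi cells, SELP, which encodes P-selectin, HDAC9, a histone deacetylase gene, and LRRC32, which encodes the TGF-beta docking receptor GARP of activated Tregs, had no reads in DN cells. They were at least 149.8-fold (adjusted p = 0.000348), 114-fold (adjusted p = 6.92e-06) and 52.4-fold (adjusted p = 0.0015) higher. RRM2, a ribonucleotide reductase gene of dividing cells, had 347 ± 130.4 scaled reads against 2.96 in DN cells (adjusted p = 0.00671). The pseudokinase gene TRIB1 had 489.8 ± 285 against 32.2 (adjusted p = 0.0194) and the vesicle trafficking gene RAB11FIP5 187 ± 91.9 against 0.235 (adjusted p = 0.00242). The DN reads of RRM2, TRIB1 and RAB11FIP5 came from 1 library each, DN replicates 3, 4 and 5, without which the mean was 0. At the other end, SORCS3, STOML1, a stomatin family gene, and ADD2, a cytoskeletal gene, had no reads in CD25hi cells. They were at least 46.7-fold (adjusted p = 0.000376), 41.1-fold (adjusted p = 0.0064) and 24.5-fold (adjusted p = 0.00586) lower than in DN cells. The DN mean fell from 117 to 75.6 for STOML1 without DN replicate 2, and from 69.6 to 46.2 for ADD2 without DN replicate 3. Log2 differences were -6.29 for DSC1 (adjusted p = 0.0416), -6.27 for EDAR (adjusted p = 0.028) and -6.15 for CACHD1 (adjusted p = 0.00586). They were -5.87 for the sarcomeric gene MYOZ3 (adjusted p = 0.00168) and -5.87 for the somatostatin receptor gene SSTR3 (adjusted p = 0.00378).

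Of the naive and central memory genes, 7 of 24 fell in CD25hi cells and none rose (18 lower and 1 higher when adjusted over the list alone). Their median was -1.31 (adjusted p = 1.61e-11, 0.00171 with an estimated correlation). NELL2 had 309 ± 134 scaled reads against 3396 ± 1423 (log2 difference -3.48, adjusted p = 0.000106). TCF7, the factor TCF-1 of naive and memory cells, had 5784 ± 1505 against 17290.1 ± 2679.5 (log2 difference -1.61, adjusted p = 0.000172). IL7R, the interleukin-7 receptor, had 17156 ± 3297 against 34232 ± 5365 (log2 difference -1.01, adjusted p = 0.0035). Of the Th2 genes 2 of 7 rose (4 when adjusted over the list alone), and the list passed (adjusted p = 8.89e-06, 0.00807 with an estimated correlation). They were the Th2 factor gene GATA3 (1084 ± 271 against 299.9 ± 233, adjusted p = 0.0269) and the skin homing receptor gene CCR4 (1650.2 ± 151 against 551 ± 321, adjusted p = 0.0305). Of the Th17 genes 2 of 10 rose (6 when adjusted over the list alone), and the list passed (adjusted p = 0.000164, 0.041 with an estimated correlation). They were CCR6 (3852 ± 479.6 against 1399 ± 561, adjusted p = 0.0158) and the interleukin-1 receptor gene IL1R1 (147 ± 80.5 against 1.07, 0 without DN replicate 4, adjusted p = 0.0182). None of the 24 cytotoxic genes passed the limma test (7 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2; list adjusted p = 0.293, and 0.0471 without DN replicate 5). The same held for the 11 Th1 genes (4 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2). Their list had an adjusted p = 0.0745. It passed with no filter (0.0226) or a term for the replicate number (0.0464), and without CD25hi replicate 3 (0.0418) or DN replicate 5 (0.0330). TBX21, on both lists, had 45.5 ± 40.6 scaled reads against 1.65 (0 without DN replicate 5, adjusted p = 0.0659, but 0.0225 without CD25hi replicate 2 and 0.0360 without DN replicate 5).

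The follicular helper list gave 4 higher and 1 lower of 19 in CD25hi cells (5 and 2 when adjusted over the list alone). Its median was 0.52 (adjusted p = 0.00158, 0.104 with an estimated correlation). TIGIT rose to 3952 ± 2547 scaled reads (adjusted p = 3.97e-05), TOX to 2716 ± 1560.0 (adjusted p = 0.000172), and MAF by 1.99 on the log2 scale (adjusted p = 0.00404). CD40LG, which encodes the helper ligand CD40L, fell to 309.9 ± 224 from 1078 ± 227 (adjusted p = 0.00543). The exhaustion factor list had 4 of 12 higher (6 when adjusted over the list alone; adjusted p = 1.78e-06, 0.00247 with an estimated correlation). The cell cycle list had 5 of 30 higher (11 when adjusted over the list alone; adjusted p = 3.72e-09, 0.041 with an estimated correlation). Its median was 2.07, but among genes with a mean of at least 1000 it was 0.19 and the test turned negative (adjusted p = 0.853). The homing receptors had 3 higher and 1 lower of 21 (10 and 2 when adjusted over the list alone; adjusted p = 7.16e-05, 0.0657 with an estimated correlation). The costimulatory receptors had 1 higher, TNFRSF9, and 1 lower, CD40LG, of 11 (3 and 1 when adjusted over the list alone; adjusted p = 0.0385, 0.148 with an estimated correlation). That list lost its call without CD25hi replicate 1 (adjusted p = 0.118), CD25hi replicate 5 (0.126), DN replicate 1 (0.0549) or DN replicate 2 (0.0662). The inhibitory receptor list was not past the threshold (2 of 14 higher, TIGIT and ENTPD1; 3 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0745). It passed with edgeR (0.0110), fry (0.0297), no filter (0.0226) and a term for the replicate number (0.0379), and without CD25hi replicate 2 (0.0313) or DN replicate 5 (0.0330). B cell markers had 2 of 7 higher, FCRL1 and IGHM (list median 3.04, adjusted p = 0.00727, 0.148 with an estimated correlation). With no filter the median was -0.07 and the call was lost (adjusted p = 0.171).

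**Figure D3:**
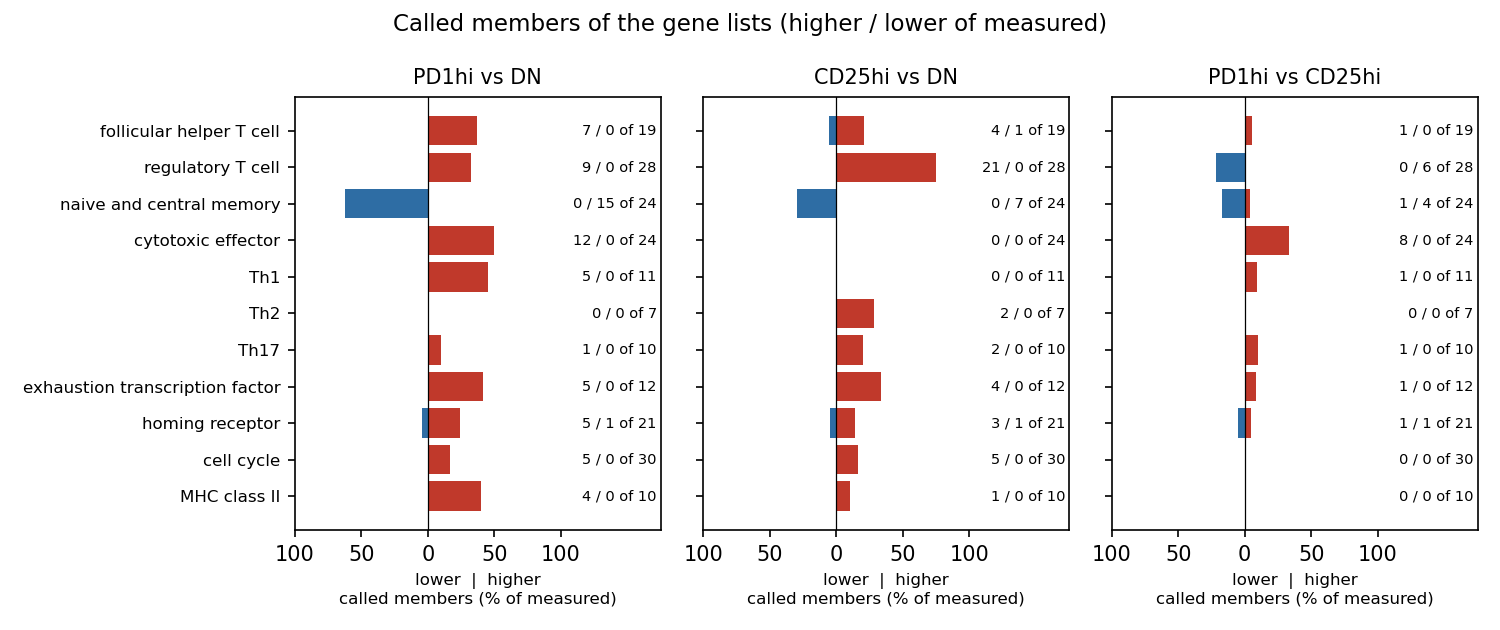
Share of the measured members of each gene list called higher (red) or lower (blue), in percent on the horizontal axis, in each of the 3 comparisons; the text beside each bar gives the members higher / lower of those measured. The Treg list reached 21 of 28 higher in CD25hi against DN, and the naive and central memory list 15 of 24 lower in PD1hi against DN.

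In CD25hi against DN cells limma called 293 genes, and 2481 had an unadjusted p under 0.05. Of the 293 genes, 291 differed in the same direction in experiment 6, 293 in experiment 7 and 293 in experiment 8. Since the calls came from these same libraries, the agreement is no independent replication. Within experiments 7 and 8 alone limma called 0 genes, and 1294 and 2135 had an unadjusted p under 0.05. Fits called 187 genes (132 higher) without CD25hi replicate 4, 180 (138 higher and 42 lower) without CD25hi replicate 5, and 48 lower genes without DN replicate 3. IL1R1 lost its call without CD25hi replicate 4 (adjusted p = 0.0613), and CCR6 without CD25hi replicate 4 or DN replicates 4 or 5 (adjusted p 0.0501 to 0.0534). TRIB1 lost it without CD25hi replicates 4 or 5 or DN replicates 3 or 5 (adjusted p 0.0515 to 0.0674). EDAR, DSC1, GATA3 and CCR4 lost it in 6, 8, 6 and 7 of 15 such fits (highest adjusted p 0.0789, 0.120, 0.0868 and 0.0823).

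PD1hi and CD25hi cells differed from each other in 85 genes, of which 35 were higher and 50 lower in PD1hi cells. The genes higher in PD1hi cells included cytotoxic genes, and those lower included Treg genes. GZMK, a granzyme of effector memory cells, had 6191 ± 1918 scaled reads in PD1hi against 77.4 ± 96.1 in CD25hi cells (log2 difference 8.61, SE 1.37, adjusted p = 0.0038). CCL5 had 15737 ± 4058 against 378 ± 195 (log2 difference 5.50, SE 0.58, adjusted p = 0.000303). In the other direction, RTKN2 had 366 ± 363 in PD1hi against 6174 ± 2680.3 in CD25hi cells (log2 difference -4.41, SE 0.56, adjusted p = 0.000696). The means were 206 for RTKN2 without PD1hi replicate 1 and 49.9 for GZMK without CD25hi replicate 1.

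Of the cytotoxic effector genes, 8 of 24 were higher in PD1hi than in CD25hi cells and none was lower (16 higher when adjusted over the list alone). They were GZMK, GZMH, NKG7, CST7, CCL3, CCL5, KLRB1 and EOMES. The list median was 2.86 (adjusted p = 7.78e-23, 0.00623 with an estimated correlation). GZMH had 1352 ± 1163 against 3.93 scaled reads (adjusted p = 0.0157). The granule gene NKG7 had 1444 ± 983 against 23.7 (adjusted p = 0.0349), and EOMES 361 ± 137 against 17.9 (adjusted p = 0.0356). Other large rises were ENC1, which encodes an actin-binding protein (1914 ± 702 against 20.4, adjusted p = 0.000349) and the receptor gene SLAMF7 of cytotoxic lymphocytes (567 ± 427 against 5.78, adjusted p = 0.0016). CRTAM, a receptor of cytotoxic T cells and a member of the CD8 T cell list, had 239 ± 134 against 1.69 (adjusted p = 0.0317). The growth factor receptor gene FGFR2 had 193 ± 263 against 0.504 (adjusted p = 0.0087), and without PD1hi replicate 1 it had 77.2 (adjusted p = 0.0269). Leaving out 1 CD25hi library moved CD25hi means to 0.297 (replicate 4) for CRTAM, 2.65 (replicate 2) for ENC1, 0.776 (replicate 2) for EOMES and 0.241 (replicate 5) for FGFR2. They became 0 (replicate 4) for GZMH, 10.5 (replicate 4) for NKG7 and 0.241 (replicate 4) for SLAMF7. The Th1 list was higher as a whole with 1 of 11 called, CCL5 (6 when adjusted over the list alone). Its median was 2.13 (adjusted p = 8.14e-09, 0.00111 with an estimated correlation). The follicular helper list was also higher, with 1 of 19 called, CD40LG at 993 ± 247 against 309.9 ± 224 scaled reads (8 when adjusted over the list alone). Its median was 0.75 (adjusted p = 2.87e-07, 0.0138 with an estimated correlation). CD40LG was not called in PD1hi against DN cells. It had 717 to 1369 scaled reads in the PD1hi libraries and 815 to 1291 in the DN libraries. Its difference between PD1hi and CD25hi cells went with a fall in CD25hi against DN cells and not with a rise in PD1hi cells.

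Of the Treg genes, 6 of 28 were lower in PD1hi than in CD25hi cells and none was higher (15 lower when adjusted over the list alone). They were FOXP3, LRRC32, RTKN2, HPGD, STAM and CSF2RB. The list median was -1.96 (adjusted p = 7.92e-18, 0.00111 with an estimated correlation). Log2 differences were -6.73 for FOXP3 (adjusted p = 0.0136), -1.93 for STAM (adjusted p = 0.00212) and -5.56 for HPGD, a prostaglandin-degrading enzyme gene (adjusted p = 0.0239). CSF2RB, the common beta chain of several cytokine receptors, had a log2 difference of -6.29 (adjusted p = 0.0356). The sort marker gene IL2RA had -8.04 (adjusted p = 0.0087). DNAH8, a dynein gene, and CEACAM4, a cell adhesion receptor gene, had no reads in PD1hi cells. They were at least 83.0-fold (adjusted p = 0.00127) and 36.2-fold (adjusted p = 0.000888) lower. Log2 differences were -6.63 for the neurofilament gene NEFL (adjusted p = 0.0016), -6.21 for RNF175 (adjusted p = 0.0016) and -5.98 for NEBL, an actin-binding gene (adjusted p = 0.0344). The Th2 list was lower in PD1hi cells with none of 7 members called in limma (3 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2; 2 lower when adjusted over the list alone). Its median was -2.09 (adjusted p = 3.89e-05, 0.0124 with an estimated correlation).

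In the naive and central memory list, 4 of 24 genes were lower in PD1hi than in CD25hi cells and 1 was higher (6 and 3 when adjusted over the list alone). The list median was -0.49 (adjusted p = 0.00543, 0.11 with an estimated correlation). TXK fell by 1.33 on the log2 scale (adjusted p = 0.00987), and NELL2 rose by 1.95 (adjusted p = 0.0317). No cell cycle gene of 30 was called in limma (4 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2; list median 0.39, adjusted p = 0.0147, 0.489 with an estimated correlation). The list lost its call without PD1hi replicate 1 (adjusted p = 0.642), PD1hi replicate 5 (0.0958), CD25hi replicate 2 (0.0814) or CD25hi replicate 4 (0.0647). A difference was not detected for the lists of inhibitory receptors (none of 14 called in limma, 6 at an unadjusted p under 0.05, 0 with edgeR and 2 with DESeq2; adjusted p = 0.271) and costimulatory receptors (1 of 11, CD40LG, adjusted p = 0.453). Nor was it for exhaustion factors (1 of 12, EOMES, adjusted p = 0.594) and Th17 genes (1 of 10, KLRB1, adjusted p = 0.73). Homing receptors had 1 higher, the integrin gene ITGA4, and 1 lower of 21 (adjusted p = 0.777). The Th17 list had a median of 0.02, a mean of -0.33 and a test in the negative direction.

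In PD1hi against CD25hi cells limma called 85 genes, and 1326 had an unadjusted p under 0.05. The direction of all 85 was the same in experiment 6, experiment 7 and experiment 8. Here too the same libraries gave the calls, so the agreement is no independent replication. Within experiments 7 and 8 alone limma called 0 genes, and 1021 and 1288 had an unadjusted p under 0.05. Fits called 54 genes (19 higher) without PD1hi replicate 5, 22 higher without PD1hi replicate 4, and 32 and 33 lower without CD25hi replicate 2 and without CD25hi replicate 4. GZMH lost its call without PD1hi replicates 1 or 5 (adjusted p 0.0555 to 0.0628), and HPGD without CD25hi replicates 1, 4 or 5 (adjusted p 0.0593 to 0.0786). CD40LG lost it without PD1hi replicates 3 or 5 or CD25hi replicates 2 or 5 (adjusted p 0.0550 to 0.0628). NKG7, CRTAM, EOMES, CSF2RB, NEBL and NELL2 lost it in 8, 8, 9, 9, 8 and 6 of 15 such fits (highest adjusted p 0.106).

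PD1hi and CD25hi cells shared 184 of their differences from DN cells, 139 higher and 45 lower in both, and no gene was called in opposite directions. The shared rises included TIGIT, TOX, MAF, PRDM1, ITGB1, IL2RB and TNFRSF1B, and the shared falls CCR7, TCF7, IL7R, EDAR, DSC1, SORCS3 and CACHD1. Independent lists of these sizes would share 4.47 higher and 0.960 lower genes. Both comparisons used the same DN libraries, so the fold changes were compared with 100 simulations. In these, PD1hi and CD25hi were unchanged from DN and shared nothing but those libraries. The simulated lists shared a mean of 0.02 genes and at most 1. Unchanged groups give almost no called genes, so this count cannot show how many genes lists as long as the real ones would share. Across 17340 genes, which are not independent replicates, the fold changes had a correlation of 0.679, against 0.523 in the simulations, and 75.6% of genes had the same sign, against 66.4%. PD1hi and CD25hi were also compared with different DN libraries, in 20 such divisions. There 11 to 29 genes were still shared in the same direction (mean 17.6), where independent lists would share a mean of 0.738. The mean correlation of the fold changes fell to 0.273 in these divisions, which used fewer DN libraries per comparison. Their covariance was 1.38 in the main fit, 0.625 in the simulations and a mean of 0.734 with different DN libraries. Part of the likeness in fold changes therefore came from the shared DN libraries. Of the 184 shared genes, 2 also differed between PD1hi and CD25hi cells, and both were named after their values were seen. FYN, a kinase of T cell receptor signalling, was higher than in DN by 1.67 in PD1hi and 0.76 in CD25hi cells on the log2 scale (0.91 between PD1hi and CD25hi, adjusted p = 0.0270). NELL2 had log2 differences from DN of -1.53 in PD1hi and -3.48 in CD25hi cells (adjusted p = 0.0317 between PD1hi and CD25hi). Of 395 genes called in PD1hi against DN alone, 48 also differed from CD25hi in the same direction; for the rest that difference was tested and not detected. Of 109 genes called in CD25hi against DN alone, 23 also differed between CD25hi and PD1hi.

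**Figure D4:**
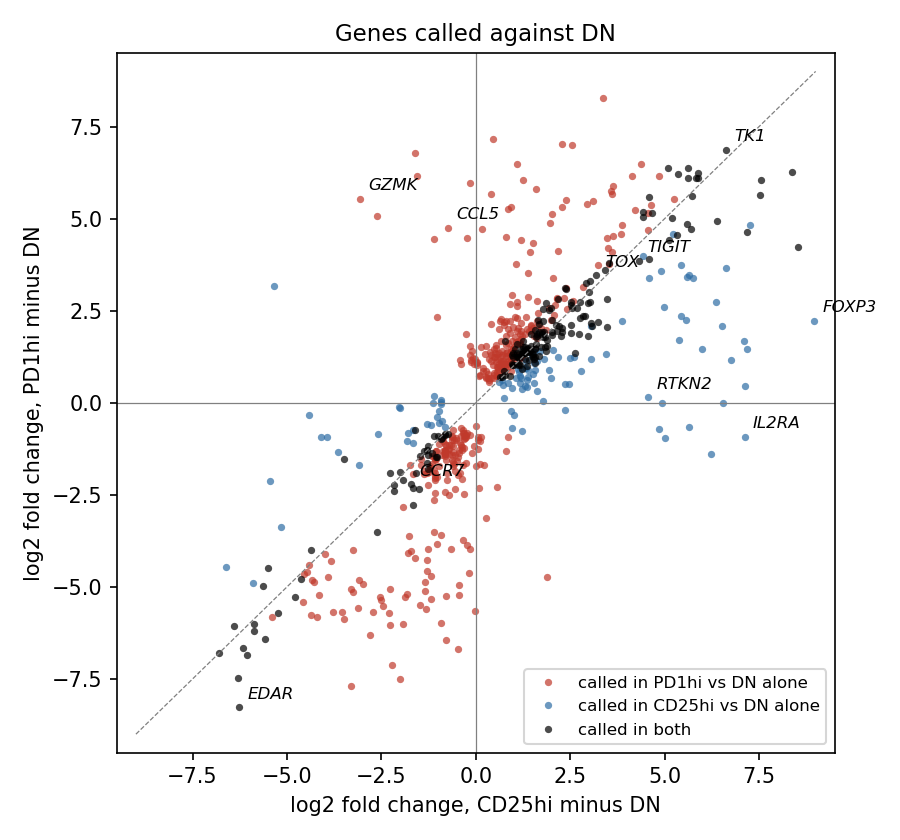
Log2 fold change of the genes called against DN, in CD25hi minus DN (horizontal axis) against PD1hi minus DN (vertical axis). Red points were called in PD1hi against DN alone, blue points in CD25hi against DN alone and black points in both. Genes called in neither comparison are not drawn, and the dashed line marks equal change. The 184 shared genes lie in the quadrants of equal sign, 139 of them higher in both.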

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

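The 6 tests of the 3 patterns below were chosen after the result was seen, while the tests on other divisions of the libraries were planned before it.

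The 225 genes lower in PD1hi than in DN cells included CCR7, LEF1 and other genes of naive cells, and the PD1hi libraries had fewer genes with a read (17196 ± 2314) than the DN libraries (18552 ± 1712; SD, n = 5). Reads in no gene were 61.2 ± 2.70% of a library's reads in PD1hi and 65.1 ± 3.79% in DN. With the number of genes detected as a covariate, the median log2 difference of these 225 was -1.81, against -1.91 without it, and 145 kept their call, which argues against fewer detected genes as the whole cause, although why the other calls were lost was not tested. Of the lower genes 82 had a mean of at least 1000 scaled reads, far above the floor of detection, with a median of -1.28. Among all tested genes, called or not, the 6109 with a mean of 10 to 50 had a median log2 difference of -0.70. With the covariate it was -0.27, and for the 2837 with a mean of at least 1000 it was 0.02 without it. Genes with few reads were thus shifted towards lower values in PD1hi cells as a whole. Of the 70 lower genes with a mean under 200, 38 (54.3%) kept their call with the covariate, so for these dropout and a real fall cannot be told apart, because few reads leave libraries at 0 in either case. A smaller share of naive cells among PD1hi cells may also give the pattern and stays open as an untested biological difference between the sorted groups.

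The cytotoxic genes of PD1hi cells, with GZMK at 6191 ± 1918 and NKG7 at 1444 ± 983 scaled reads, could come from CD8 T cells or NK cells, which the CD4 gate would remove. CD8A (16.7 scaled reads) and CD8B (0.163) together made up 0.273% of GZMK, which argues against CD8 T cells, although CRTAM, a marker on the CD8 list that activated CD4 T cells also express, had 239 ± 134. CD8A and CD8B each had reads in 1 PD1hi library alone, CD8A with 83.7 scaled reads there. The NK genes FCER1G (0.163), TYROBP (7.44), KLRF1 (11.6), FCGR3A (10.9) and NCAM1 (28.0) together made up 4.02% of NKG7. This argues against NK cells as far as these genes show, but they were chosen after the result was seen. FCER1G, FCGR3A and NCAM1 each had reads in 1 PD1hi library alone. On the NK list, FCER1G and TYROBP also stand on the monocyte list. KIR3DL2, at 80.5 scaled reads in PD1hi cells, was the NK list member with most reads there. It was left out of the sum, and with it the share of NKG7 would be higher, so the outcome depends on the genes chosen. Expression by CD4+ PD1hi cells themselves stays open as the untested biological explanation.

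The 139 genes higher in both PD1hi and CD25hi cells than in DN cells could reflect CD25hi cells in the PD1hi sort, which the CD25 gate would remove. The excess over DN in PD1hi cells, as a share of that in CD25hi cells, was 3.22% for FOXP3 (upper 95% limit 40.7%) and -0.616% for IL2RA (upper limit 8.02%), the markers named before the values were seen. Of the shared genes 95.7% (133 of 139) lay above the higher limit, with a median of 102% (TOX 118%, TNFRSF1B 119%, IL2RB 77.9%, ITGB1 77.9%, TIGIT 67.2%). These genes were selected for being called higher in PD1hi cells, which favours large shares, so that count and median were partly built in. The low shares of IL2RA and FOXP3 argue against admixed CD25hi cells as the only source of an excess this large. With different DN libraries at least 11 genes, higher and lower together, were shared in the same direction. That was above the highest number expected of independent lists, 2.13, which argues against the shared DN libraries as the whole cause. These fits used fewer DN libraries per comparison and shared 11 to 29 genes, against 184 in the main fit. They therefore do not show how many of the 139 genes would be shared without common DN libraries. An activated or memory state common to both groups stays open as an untested biological explanation.

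In each comparison no other tested division of the libraries gave as many changed genes as the real one. Mixed divisions hold libraries of both groups on each side, which adds spread and leaves few calls. The divisions therefore bear on whether the groups differed at all, and not on how many of the called genes are false. In PD1hi against DN, 1 of 100 divisions of the 10 libraries, the real one, gave as many genes (579; the highest of the others gave 2). In CD25hi against DN it was again 1 of 100 (293, against 5), and in PD1hi against CD25hi 1 of 100 (85, against 4).

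Single libraries were marked where they stood apart from the other 4 of their group by a gap of more than 0.71 of the group's range. For genes the gap and range were taken on log2 of scaled reads plus 1, although the values listed are scaled reads. A library was marked in 62 of 459 groups (13.5%). Of these, 21 were in PD1hi, 19 in CD25hi and 22 in DN. The 459 include genes with no reads in any library of a group, where no library can be marked. Among the remaining groups the marked share was therefore higher. Chance marks about 1 in 20 groups, and genes with reads in a single library are marked by construction. The 459 groups covered 146 named genes and 7 measures of the libraries, and none of those measures was marked. In PD1hi cells, reads came from 1 library alone for EDAR (61.7 scaled reads in replicate 3), DSC1 (52.7 in replicate 2), NBEA (10.8 in replicate 3), CACHD1 (4.89 in replicate 3) and FCER1G (0.815 in replicate 5). The same held for FCGR3A (54.3 in replicate 1), ITGA2B (128 in replicate 3), SSTR3 (3.92 in replicate 3), ADD2 (8.81 in replicate 3), SCARNA3 (49.7 in replicate 4) and NEBL (3.32 in replicate 4). PD1hi values stood high for DUSP2 (3740.1 in replicate 4) and CSF2RB (94.9 in replicate 2). PD1hi values stood low for RRM2 (0 in replicate 4), HLA-DRB1 (967 in replicate 2), MS4A1 (0 in replicate 1), TUBB1 (0 in replicate 2), TRIB1 (0 in replicate 2), HSPA1A (3.45 in replicate 2), MT-ATP6 (9699.5 in replicate 3) and HPGD (0 in replicate 1).

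In CD25hi cells, reads came from 1 library alone for GZMH (19.7 in replicate 4), RCAN2 (44.5 in replicate 4), CACHD1 (32.8 in replicate 3) and CCL3 (3.10 in replicate 4). The same held for ITGA2B (70.3 in replicate 3), MYOZ3 (2.07 in replicate 4), SSTR3 (7.24 in replicate 4), UBE2C (28.96 in replicate 4) and IL21 (1.19 in replicate 2). Values stood high for ACTN1 (1364 in replicate 1) and SLAMF7 (27.9 in replicate 4). Values stood low for GZMA (0.963 in replicate 3), NBEA (0 in replicate 1), TXK (1893 in replicate 5), CD79A (0 in replicate 5), FCER1G (0.963 in replicate 3), SCARNA17 (0 in replicate 3), STAM (2283 in replicate 3) and HSPA1B (7.12 in replicate 2).

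In DN cells, reads came from 1 library alone for EOMES (74.2 in replicate 2), TK1 (35.4 in replicate 1), TBX21 (8.24 in replicate 5) and CCR3 (16.9 in replicate 3). The same held for RRM2 (14.8 in replicate 3), IL12A (85.1 in replicate 2), MS4A1 (25.4 in replicate 3) and HBB (69.1 in replicate 2). It also held for SNORA12 (1.69 in replicate 2), TRIB1 (161 in replicate 4), RAB11FIP5 (1.18 in replicate 5) and IL1R1 (5.37 in replicate 4). Values stood high for F2R (54.1 in replicate 5), FCER1G (110.1 in replicate 3) and NEBL (53.7 in replicate 4). Values stood low for SORCS3 (27.0 in replicate 2), CSF1R (0 in replicate 1), MMD (78.4 in replicate 2), ENTPD1 (148 in replicate 2), NEFL (28.2 in replicate 5), IFITM1 (3878 in replicate 4) and LDHA (5848 in replicate 4).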

How the results depend on the processing

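The fits without the 3 least correlated libraries, with the genes-detected covariate, with a mean of at least 1000 and within experiments 7 and 8 were chosen after seeing the data; all others were planned. Every called gene that was tested under an alternative kept its direction, and no named gene reversed. Apart from fits without 1 library, 129 gene counts stayed within 1.5 times the reported count, 14 were larger and 37 smaller. Of 55, 41 and 27 named calls in PD1hi against DN, CD25hi against DN and PD1hi against CD25hi, 41, 30 and 15 were kept with every library left out in turn, and edgeR made 39, 26 and 15 of them. Quantile normalization moved the median log2 difference of all genes in PD1hi against DN from -0.16 to -0.03. In simulated data 2 of 61 genes changed by 1 on the log2 scale were called, and 1 of 8 with a mean of at least 1000, so changes of this size were mostly missed; depth was not varied.

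The cause of the following differences was not tested, except that fewer libraries or genes were tested where the setting says so. With DESeq2 the changed, higher and lower genes numbered 1062, 596 and 466 in PD1hi against DN, 681, 437 and 244 in CD25hi against DN, and 293, 139 and 154 in PD1hi against CD25hi, with 370 shared between the comparisons with DN. With a constant prior variance they numbered 344, 201 and 143, then 149, 112 and 37, then 50, 17 and 33, with 91 shared. With edgeR the lower genes numbered 128 in PD1hi against DN and 37 in CD25hi against DN, and PD1hi against CD25hi gave 51, 21 higher and 30 lower. Within experiment 7 alone and within experiment 8 alone, with 2 libraries per group, limma called 0 changed, 0 higher and 0 lower genes in each comparison and 0 shared genes; the genes with an unadjusted p under 0.05 numbered 1794 and 3000, 1294 and 2135, and 1021 and 1288 in the 3 comparisons. A test of whether the differences between groups were unlike in experiments 7 and 8 called 0 genes in limma, with 1519, 947 and 661 at an unadjusted p under 0.05. With an experiment term 116 genes were lower in CD25hi against DN and 54 higher in PD1hi against CD25hi. With only the 2 groups compared 23 genes were higher in PD1hi against CD25hi. Without the 3 least correlated libraries PD1hi against DN gave 251 genes, 166 higher and 85 lower, and CD25hi against DN 49 lower genes. With a term for the replicate number the counts were 809, 403 and 138, the last with 61 higher and 77 lower; same-numbered libraries of different groups had residual correlations of -0.0244 to 0.135 (mean 0.0572, against -0.0143 for other pairs), and 6 of 15 such pairs lay over 0.1. Of 15 libraries 10 had their best partner in another group under their own number, more than random matching would give. Not every pair was that close, but pairing is possible, and the reported gene counts do not take it into account.

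Of 27 lists, 19, 15 and 9 passed the threshold in the 3 comparisons. An estimated correlation left 9 in PD1hi against DN and 6 in CD25hi against DN, and the follicular helper list in CD25hi against DN (median 0.52) lost its call (adjusted p = 0.104; over all settings 3.7e-05 to 0.104). A mean of at least 1000 left 9, 7 and 4 lists, with fewer genes tested. In PD1hi against DN costimulatory receptors (0.125), Th17 (0.0646), homing receptors (0.535), cell cycle (0.215), interferon response (0.525) and oxidative phosphorylation (0.0768) lost their call there. So did costimulatory receptors (0.0717), homing receptors (0.403), glycolysis (0.403) and oxidative phosphorylation (0.403) in CD25hi against DN, and naive and central memory (0.101) and cell cycle genes (0.0570) in PD1hi against CD25hi. In CD25hi against DN that setting reversed the test of the cell cycle list (median 0.19, adjusted p = 0.853; 4.95e-12 to 0.853 over all settings) and of the interferon response list (median 0.34, adjusted p = 0.937; 0.00679 to 0.937).

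Other settings chosen before the data were seen changed the call of these lists, with adjusted p values given. In PD1hi against DN a mean of at least 50 ended the call of interferon response (0.0697) and made that of B cell genes (0.0282). In that comparison fry ended the calls of interferon response (0.0522), oxidative phosphorylation (0.0548) and ribosomal protein genes (0.170), and edgeR those of dendritic cell (0.0691) and histone genes (0.0650). In CD25hi against DN a mean of at least 50 ended the calls of costimulatory receptors (0.0592), interferon response (0.0592) and oxidative phosphorylation (0.0520). Quantile normalization ended those of costimulatory receptors (0.0907), interferon response (0.0831), glycolysis (0.0831) and oxidative phosphorylation (0.101). There fry ended those of interferon response (0.0984), glycolysis (0.0927), oxidative phosphorylation (0.167) and ribosomal protein genes (0.243), and a fit of only the 2 groups that of interferon response (0.0697). With no filter the B cell call was lost (0.171), and inhibitory receptors (0.0226), Th1 (0.0226), dendritic cell (0.0250) and histone genes (0.00844) passed. The term for the replicate number let inhibitory receptors (0.0379) and Th1 genes (0.0464) pass in CD25hi against DN and changed the call of no other list. In PD1hi against CD25hi a mean of at least 50 (0.0553) and fry (0.505) ended the cell cycle call, fry that of glycolysis (0.296) and no filter that of helper cytokines (0.0651). Monocyte genes passed there with a pseudocount of 5 (0.0469), no filter (0.00888) or quantile normalization (0.0468). Of the settings chosen later, the genes-detected covariate ended the calls of interferon response (0.0583), dendritic cell (0.0629) and histone genes (0.0583) in PD1hi against DN. It also ended those of costimulatory receptors (0.0728), interferon response (0.0862), glycolysis (0.0572) and oxidative phosphorylation (0.0944) in CD25hi against DN and of glycolysis in PD1hi against CD25hi (0.0543). Without the 3 least correlated libraries, interferon response (0.384), oxidative phosphorylation (0.0919), dendritic cell (0.0620) and histone genes (0.166) lost their call in PD1hi against DN, and interferon response (0.423), glycolysis (0.300) and oxidative phosphorylation (0.244) in CD25hi against DN. Inhibitory receptors in CD25hi against DN (0.0456) and ribosomal protein genes in PD1hi against CD25hi (0.00194) passed there.

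With each library left out in turn, changed, higher and lower genes ranged over 360 to 679, 223 to 404 and 137 to 275 in PD1hi against DN, 180 to 327, 132 to 239 and 42 to 88 in CD25hi against DN, and 54 to 88, 19 to 37 and 32 to 54 in PD1hi against CD25hi. Shared genes ranged from 124 to 192. The median of the follicular helper list ranged over 1.28 to 1.64, 0.35 to 0.82 and 0.39 to 1.11 in these comparisons, and that of the regulatory T cell list over 1.48 to 1.92, 3.95 to 4.51 and -2.39 to -1.86. Lists past the threshold numbered 16 to 20, 11 to 17 and 7 to 11.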

Other observations

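All lists and tests in this part were planned before the result was seen. For the lists with no gene called in limma edgeR called 0 genes as well and DESeq2 at most 2, and the number at an unadjusted p under 0.05, where it is not given, was at most 4. Antigen presentation genes were higher in PD1hi cells, where 4 of 10 MHC class II genes rose against DN (6 when adjusted over the list alone). The list median was 2.03 (adjusted p = 1.68e-06, 0.0553 with an estimated correlation). CD74, the invariant chain, had 15940.4 ± 6823 scaled reads against 4041 ± 1438 (adjusted p = 0.00272). On the log2 scale HLA-DRB1 was higher by 2.58 (adjusted p = 0.0146), HLA-DPB1 by 2.39 (adjusted p = 0.0213) and HLA-DPA1 by 2.11 (adjusted p = 0.039). How reads divided between HLA paralogs was not tested, and neither was a share of B cells. The B cell genes CD79B and MS4A1 had more reads in PD1hi than in DN cells. The B cell list was higher in CD25hi than in DN cells (median 3.04, adjusted p = 0.00727, 0.148 with an estimated correlation). With no filter its median was -0.07 and the call was lost (adjusted p = 0.171). In CD25hi cells 1 of 10 MHC class II genes rose, HLA-DRB1 (8 when adjusted over the list alone). There the list median was 1.97 (adjusted p = 1.57e-06, 0.0844 with an estimated correlation). Between PD1hi and CD25hi none was called in limma (1 unadjusted, median -0.01, adjusted p = 0.759). Helper cytokine genes rose in PD1hi cells, 2 of 9 against DN (4 when adjusted over the list alone). That list passed (adjusted p = 0.00248, 0.0181 with an estimated correlation). IFNG, which encodes interferon gamma, had 1061 ± 755 scaled reads against 51.0 in DN (20.9 without DN replicate 2, adjusted p = 0.0342). IL12A, a subunit of interleukin-12 and interleukin-35, had 123 ± 56.7 against 17.02 (0 without DN replicate 2, adjusted p = 0.0429). The cytokine list was also higher against CD25hi with none of 9 members called in limma (2 unadjusted, 2 when adjusted over the list alone). Its median there was 2.32 (adjusted p = 0.0024, 0.0164 with an estimated correlation). A difference between CD25hi and DN was not detected (adjusted p = 0.425).

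Of the metabolic genes, 3 of 17 glycolysis genes rose in PD1hi against DN, GAPDH, PFKP and PFKL (7 when adjusted over the list alone). The list median was 0.48 (adjusted p = 5.2e-05, 0.0553 with an estimated correlation). Of 28 oxidative phosphorylation genes 2 rose, COX6A1 and ATP5B (3 when adjusted over the list alone). Their median was 0.30 (adjusted p = 0.00113, 0.225 with an estimated correlation). GAPDH, a glycolytic enzyme, was higher by 1.13 (adjusted p = 0.0103). Neither list, in CD25hi against DN, had a called gene in limma (8 and 5 unadjusted). Glycolysis had an adjusted p = 0.0126 (0.234 with an estimated correlation) and oxidative phosphorylation 0.0109 (0.355 with an estimated correlation). Leaving out CD25hi replicate 1 or DN replicate 4 ended both calls (glycolysis adjusted p = 0.126 and 0.0634, oxidative phosphorylation 0.164 and 0.0798). In PD1hi against CD25hi the glycolysis list had no called gene in limma (1 unadjusted, adjusted p = 0.0275, 0.473 with an estimated correlation). It lost its call without any 1 of PD1hi replicates 1, 3 and 5 and CD25hi replicates 2, 3 and 4 (adjusted p 0.0628 to 0.137). Oxidative phosphorylation had a median of 0.02, a mean of -0.01 and an adjusted p = 0.439, but 0.0139 without CD25hi replicate 1.

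Interferon response genes had 1 of 23 higher in PD1hi against DN, OASL (545 ± 66.7 against 52.2 scaled reads, 33.1 without DN replicate 2, adjusted p = 0.00804). The list had an adjusted p = 0.0148 (0.0952 with an estimated correlation), and 0.0599 without DN replicate 5. In CD25hi against DN 1 rose, OAS1 (adjusted p = 0.037; list adjusted p = 0.0345, 0.159 with an estimated correlation). The list lost its call without PD1hi replicate 4 (0.0535), CD25hi replicate 1 (0.171), DN replicate 4 (0.0581) or DN replicate 5 (0.0869). PD1hi against CD25hi gave a median of -0.03 and a mean of 0.08 (adjusted p = 0.759). Of the 20 immediate early genes DUSP2, a phosphatase gene, rose in PD1hi against DN (1547 ± 1227 against 458, 999 without PD1hi replicate 4, adjusted p = 0.0371). The list was not past the threshold in any comparison (adjusted p = 0.195 for PD1hi against DN, though 0.0389 without PD1hi replicate 3, 0.39 for CD25hi against DN and 0.73 for PD1hi against CD25hi). In the last the median was 0.08 and the mean -0.09.

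Ribosomal protein genes were lower in PD1hi against DN, with 2 of 87 called, among them RPS13 (log2 difference -0.67, adjusted p = 0.0116). The list median was -0.29 (adjusted p = 0.000595, 0.591 with an estimated correlation). None was called by limma in CD25hi against DN (13 unadjusted, median -0.22, adjusted p = 0.00118, 0.641 with an estimated correlation). A difference between PD1hi and CD25hi was not detected (adjusted p = 0.73, but 0.00157 without PD1hi replicate 4). Histone genes had none of 30 called in limma (6, 3 and 0 unadjusted in the 3 comparisons). Their list had a median of 0.50 in PD1hi against DN (adjusted p = 0.0143, 0.0589 with an estimated correlation, 0.0599 without DN replicate 5). It did not pass in CD25hi against DN (adjusted p = 0.0954, but 0.0453 without CD25hi replicate 4 and 0.0172 without DN replicate 1) or PD1hi against CD25hi (adjusted p = 0.411). The 13 mitochondrially encoded genes did not pass in PD1hi against DN (median -0.08, test in the positive direction, adjusted p = 0.782). Nor did they in CD25hi against DN (adjusted p = 0.239) or PD1hi against CD25hi (adjusted p = 0.453). The 8 small RNA genes did not pass in PD1hi against DN (median -0.19, test in the positive direction, adjusted p = 0.883). Their adjusted p values were 0.631 in CD25hi against DN and 0.759 in PD1hi against CD25hi.

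Among markers of other blood cells, 1 of 7 B cell genes rose in PD1hi against DN, CD79B (738 ± 211 against 209.9 scaled reads, adjusted p = 0.0411; list adjusted p = 0.104, but 0.0293 without PD1hi replicate 1). MS4A1 had 225 ± 194 scaled reads in PD1hi against 5.08 in DN cells (0 without DN replicate 3, adjusted p = 0.0661, but 0.00501 without PD1hi replicate 1 and 0.0396 without DN replicate 3). CD79A had 21.3 against 35.6 (adjusted p = 0.899), with means of 12.9 without PD1hi replicate 3 and 16.4 without DN replicate 3. PD1hi against CD25hi had 1 lower, FCRL1 (list median 0.05, mean -1.19, test negative, adjusted p = 0.286, but 0.0119 without PD1hi replicate 3). Dendritic cell genes were lower in PD1hi against DN with none of 5 called in limma (2 unadjusted, median -2.82, adjusted p = 0.0228, 0.149 with an estimated correlation). That call was lost without PD1hi replicate 4 (adjusted p = 0.0626) or DN replicate 5 (adjusted p = 0.0849). They did not pass in CD25hi against DN (adjusted p = 0.0745, but 0.0474 without CD25hi replicate 4 and 0.0147 without DN replicate 4) or PD1hi against CD25hi (adjusted p = 0.619). Monocyte genes had none of 8 called in limma (1, 1 and 2 unadjusted, adjusted p = 0.392 for PD1hi against DN and 0.065 for PD1hi against CD25hi). Their median in CD25hi against DN was -0.10 and their mean 0.59 (adjusted p = 0.39). The list passed in PD1hi against CD25hi without PD1hi replicate 3 (0.00856), CD25hi replicate 1 (0.0254), CD25hi replicate 3 (0.0136) or DN replicate 3 (0.0483). The abundant monocyte gene LYZ was at 80.0 scaled reads in PD1hi (47.5 without PD1hi replicate 4) and 291 in DN cells. NK markers did not pass in CD25hi against DN (adjusted p = 0.45) or PD1hi against CD25hi (median 0.22, mean -0.60, test negative, adjusted p = 0.73). The 3 platelet genes did not pass (adjusted p = 0.883 for PD1hi against DN). Their median in CD25hi against DN was 0.02 and their mean -0.07 (adjusted p = 0.907). In PD1hi against CD25hi these were 0.17 and -0.04 (adjusted p = 0.759). The CD8 T cell list had 1 measured gene, CRTAM, and the erythroid list 2, so neither was tested.

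With single libraries left out, some calls were lost, in the number of fits of 15 given here with the highest adjusted p. In PD1hi against DN these were HLA-DPB1 (2, 0.0628), HLA-DPA1 (7, 0.0994), IFNG (8, 0.0919), IL12A (10, 0.0981), PFKP (6, 0.0670), PFKL (8, 0.0840), COX6A1 (3, 0.0638), ATP5B (4, 0.0774), CD79B (9, 0.0969) and DUSP2 (7, 0.0894). In CD25hi against DN these were OAS1 (9, 0.118) and HLA-DRB1 (5, 0.0868), both higher in 4 of 5 same-numbered pairs. In PD1hi against CD25hi and CD25hi against DN, calls on the report's lists lost in the same way were FOXP1 (3, 0.0552), CCL3 (5, 0.0628), KLRB1 (8, 0.0927), BUB1B (11, 0.127) and MKI67 (11, 0.109), and in PD1hi against DN RRM2 (5, 0.0732), higher in 4 of 5 pairs like BUB1B in CD25hi against DN. Calls were gained without 1 library for MT-CO1 (DN replicate 2, 0.0482), HIST1H1B (PD1hi replicate 2, 0.0499, or DN replicate 4, 0.0376) and HIST1H1E (DN replicate 2, 0.0352) in PD1hi against DN. The same held in CD25hi against DN for HSPA1B (DN replicate 1, 0.0328), FCER1G (CD25hi replicate 3, 0.0318) and RPL39L (CD25hi replicate 3, 0.0489). In PD1hi against CD25hi it held for ENTPD1 (DN replicate 2, 0.0179), CCR4 (PD1hi replicate 3, 0.0432, or DN replicate 2, 0.0442), DUSP2 (CD25hi replicate 5, 0.0269) and FCER1G (CD25hi replicate 3, 0.00480, or DN replicate 3, 0.0366). With genes at 0 in 1 group set to their bound, list medians stayed the same except for B cell genes in PD1hi against DN (1.77, from 1.17) and cytotoxic genes in CD25hi against DN (0.13, from 0.28).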
